A study of Mus musculus with 9 samples.

How the data were processed

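Polyadenylated RNA was sequenced from bone marrow-derived macrophages, which are primary macrophages grown from mouse bone marrow. Per the labels, marrow cells were differentiated over 7 days with 30% supernatant of L929 cells, a source of macrophage colony-stimulating factor, and were then treated with interferon-gamma at 40 ng/ml for 12 h. There were 3 genotypes with 3 libraries each: wild type, a knockout of the Ndufa4l3-miR147 gene (also called Nmes1, listed under the symbol AA467197) and a knockout of Ndufa4. The labels state RNA integrity numbers above 9 for the RNA used and call the replicates technical. The p-values given here therefore measure only the spread between libraries, which may be technical, and not the spread between mice.

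The values analysed were TPM, a length-normalised abundance that sums to the same total in every library, as deposited by the authors in 1 table of 29763 named genes. Per the submitters' processing notes, kallisto, DESeq2 and edgeR were used, with no version or role stated, and both mm10 and GRCm39 were named as genome builds. Kallisto estimates transcript abundance by matching reads to a transcript set without a genome alignment. The annotation release, the read filters and the way transcripts were summed to genes are not given in the sources used here. The TPM of each library in the table summed to between 913497 and 921705, so 7.83% to 8.65% of each library lay on transcripts outside the table. One entry without a gene name, at most 0.003% of a library, was left out, and 8730 entries were listed at 0 in every library. TPM keep no read depth, so the depth of the libraries is unknown and no counting interval is given. Because TPM are shares of a fixed total, a gain in some abundant genes lowers every other value. Because they are divided by a modelled transcript length, libraries that differ in their coverage of long transcripts differ in TPM as well. Near-identical paralogs can share reads, so single values within such families are uncertain.

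Values were transformed to log2(TPM + 1), and genes with at least 1 TPM in at least 3 of the 9 libraries were kept, which left 11133. Fold changes are on this scale, which understates the change of genes with low TPM. A linear model with 1 mean per genotype was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step. All libraries shared 1 estimate of the spread because 3 per group leave few degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes kept, with two-sided tests, and calls of at least a 2-fold change were counted separately. The 3 comparisons were each knockout against wild type and the Ndufa4l3-miR147 knockout against the Ndufa4 knockout.

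Gene lists were fixed before the data were examined and covered interferon responses, antigen presentation, chemokines and cytokines, innate sensing, the respiratory chain, ribosomes, carbon and lipid metabolism, stress responses, the cell cycle and markers of other cell types. Of their members, 1073 of 1076 were found, 9 of them by an older symbol. Lists with at least 5 members kept, 35 in all, were tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Beside this stand camera with an estimated correlation, fry (a rotation test of whether a list moves 1 way, without reference to other genes) and the count of members called when p-values were adjusted over the list alone. At the preset correlation, up to 9, 16 and 11 lists were also called when libraries were regrouped across genotypes in the 3 comparisons. A camera call alone therefore does not tie a list to genotype. The marker lists for lymphocytes and NK cells and for erythroid, megakaryocyte, basophil and mast cells kept 4 members each and were not tested. The list of cytosolic ribosomal proteins was defined by a symbol pattern and also took in 7 ribosomal protein S6 kinases among its 97 members kept.

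The genes named were chosen by a rule fixed before the data were examined: the targeted genes, the 12 largest rises and 12 largest falls for each knockout against wild type (8 and 8 between the knockouts) among called genes with at least 5 TPM in the higher group and no overlap between the libraries of both groups (without symbols of unnamed gene models, such as those ending in Rik), and for each list up to 2 called members per direction with the smallest adjusted p, or the 2 most abundant members where none was called. Genes named outside this rule are stated to have been chosen after their values were seen. Both comparisons against wild type share their control libraries. The correlation and covariance of their changes were therefore set beside 100 draws in which all 9 libraries, the shared controls included, were simulated unchanged.

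The procedure was tested on simulated data with the real mean of each gene, independent noise and 50 changed genes for each fold. Each gene had 1 spread for all genotypes. Real spreads differed between genotypes, and the estimated correlation within a list was up to 0.77. The recoveries and false calls below hold for the simpler setting and may not carry over to the real libraries. At 1.5-fold, 37 of 50 were recovered in the setting of the Ndufa4l3-miR147 knockout against wild type, 33 in that of the Ndufa4 knockout against wild type and 34 in that of knockout against knockout. At 2-fold, 47, 46 and 47 were recovered. Over all folds together, 15, 8 and 6 unchanged genes were among 197, 185 and 184 calls. A gene list lowered by 0.2 was called by camera in each setting, and in that of the Ndufa4l3-miR147 knockout against wild type 1 list that had not been shifted was called as well, against 0 in the others.

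Alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter on low values and a filter at 5 TPM, median-of-ratios scaling, quantile normalization, removal of mitochondrially encoded and ribosomal protein genes, limma without a trend, a fit to only the 6 libraries compared, the replicate number as a block, and leaving out each library in turn. After the data were seen, library weights, Ndufa4 knockout replicate 3 left out together with median-of-ratios scaling, and removal of each library's trend on transcript length and GC content (natural splines) were added. Gene positions, transcript lengths, GC content and 3 prime UTRs came from GENCODE M21 on GRCm38, in which 96.9% of the genes had a single position. The build and release behind the TPM may differ, so these positions are those of GRCm38 and not of the table. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.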

Results

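Transcript abundance was measured in macrophages of 3 genotypes, 3 libraries each, all taken after 12 h of interferon-gamma. The series concerns a change in the make-up of mitochondrial complex IV in macrophages and its relation to interferon signalling. Ndufa4 is a subunit associated with complex IV, the cytochrome c oxidase of the respiratory chain. The Ndufa4l3 gene encodes a related small protein and carries the microRNA miR-147. All libraries were stimulated, so the values describe differences between genotypes in interferon-treated cells and not the response to interferon itself. Between 10809 and 10959 genes reached at least 1 TPM in a library. TPM are given as mean ± SD and log2 fold changes as estimate ± SE, with n = 3 libraries per genotype.

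The libraries of wild type and of the Ndufa4l3-miR147 knockout lay close together. Those of the Ndufa4 knockout lay farther from them but did not form a tight group. Its replicate 2 had a median log2 difference of 0.117 from Ndufa4l3-miR147 knockout replicate 2. From replicates 1 and 3 of its own genotype it differed by 0.131 and 0.207. On the second principal component its replicates 1 and 2 lay at -21.1 and -16.2. Replicate 3 lay at 8.95 there, near wild-type replicate 2 at 8.24. On the first principal component, with 34.5% of the variance, Ndufa4 knockout replicate 3 lay at 40.4 and the other 8 libraries between -11.4 and 4.56. In that library the upper quartile of TPM was 7.79, against 9.24 to 9.84 in the others. Its genes with long transcripts were lower and those with short transcripts higher than in the other libraries of its genotype, with a Spearman rho of -0.535 between deviation and transcript length across 11049 genes, which are not independent replicates.

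**Figure D1:**
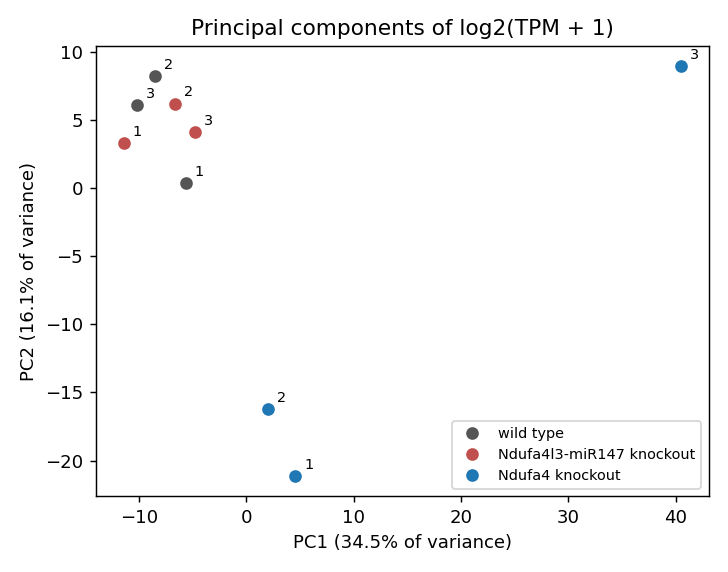
Scores of the 9 libraries on the first principal components of log2(TPM + 1), which hold 34.5% and 16.1% of the variance, with colour for genotype and the replicate number beside each point. Ndufa4 knockout replicate 3 lies at 40.4 on the first component, and the other 8 libraries lie between -11.4 and 4.56.

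The targeted gene of the first knockout, AA467197 (Ndufa4l3; ENSMUSG00000033213.16, protein coding, GRCm38 chromosome 2, 122636986 to 122641191, plus strand), was at 360 ± 5.24 TPM in wild type and at 3.21 ± 1.18 TPM in its knockout. The fall was -6.46 ± 0.16 (limma adjusted p = 1.8e-07). In the Ndufa4 knockout it was at 506 ± 29.6 TPM, a difference of 0.49 ± 0.16 from wild type that did not pass the test (limma adjusted p = 0.094). The libraries did not overlap, at 355 to 365 TPM in wild type and 472 to 527 TPM in the Ndufa4 knockout. The SE was pooled with the Ndufa4l3-miR147 knockout libraries, at 2.21 to 4.50 TPM, so the failed test does not show an unchanged level. Ndufa4 (ENSMUSG00000029632.7, protein coding, GRCm38 chromosome 6, 11900292 to 11907497, minus strand) was listed at 0, 0.303 and 0 TPM in wild-type replicates 1 to 3, at 0, 0.621 and 0 TPM in the Ndufa4l3-miR147 knockout and at 0 TPM in each library of the Ndufa4 knockout. Ndufa4 is a gene that most cells express, so these entries check nothing about the Ndufa4 labels. The mature microRNA miR-147 was not analysed here. Genes of the Y chromosome were detected in all 9 libraries and were lowest in Ndufa4 knockout replicate 3: Ddx3y was at 13.2 TPM there and at 21.4 to 27.7 TPM elsewhere, Uty at 4.37 and 8.94 to 10.8, Kdm5d at 5.03 and 8.46 to 10.6, and Eif2s3y at 43.1 and 53.2 to 66.8.

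The first comparison set the Ndufa4l3-miR147 knockout against wild type. With replicates called technical, it cannot tell an effect of the loss from other differences between the cells of both genotypes. Beside the target, Ctse (cathepsin E, an endosomal aspartic protease) rose most, from 64.8 ± 0.695 to 156 ± 6.26 TPM, or 1.25 ± 0.12. Plau (urokinase) rose by 0.77 ± 0.06 to 529 ± 11.4 TPM and Steap3 (an endosomal iron reductase) by 0.65 ± 0.05. Ppfia4, a liprin scaffold protein, fell from 11.9 ± 1.52 to 0.203 ± 0.0854 TPM, or -3.41 ± 0.11. Dbi, an acyl-CoA binding protein, fell by -0.94 ± 0.07 from 238 ± 11.8 TPM, and Ighm, Fcgr2b (the inhibitory IgG receptor) and Apeh (a peptidase) fell by -0.65 ± 0.07, -0.64 ± 0.07 and -0.61 ± 0.06. The limma adjusted p of these genes lay between 9.5e-07 and 0.0046. Ctse, Steap3, Ppfia4 and Dbi lie near each other on chromosome 1, while the targeted gene lies on chromosome 2. A background segment that differs between the mice was not tested as their cause.

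In all, 48 of 11133 genes were called, 27 higher and 21 lower. Of these, 7 changed at least 2-fold, 1 upward and 6 downward. At an unadjusted p under 0.05 there were 917 genes. Further called rises with at least 5 TPM were those of Tmeff1, Tgfb3, Xlr, Ccl7, Id1, Ccl4, Nanos1, Metrnl and Lipg, between 0.53 and 0.88. Further falls were those of Slco4a1 (an organic anion transporter, -1.49 ± 0.20), Fads2 (a fatty acid desaturase, -0.69 ± 0.09), Pla2g7, Ube2t and Mfge8. The naming rule left out 5430435G22Rik for its symbol. It was named after its values were seen, and fell by -0.85 ± 0.07 from 208 ± 6.53 TPM (limma adjusted p = 9.9e-04). Of the 30 named genes called, 10 kept their call in every alternative, and 20 lost it without at least 1 library, with limma adjusted p of up to 0.213. The count itself was 13 to 26 when any 1 library of the genotypes compared was left out, 75 without Ndufa4 knockout replicate 1, 198 without Ndufa4 knockout replicate 3, and 306 when only the 6 libraries compared were fitted.

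**Figure D2:**
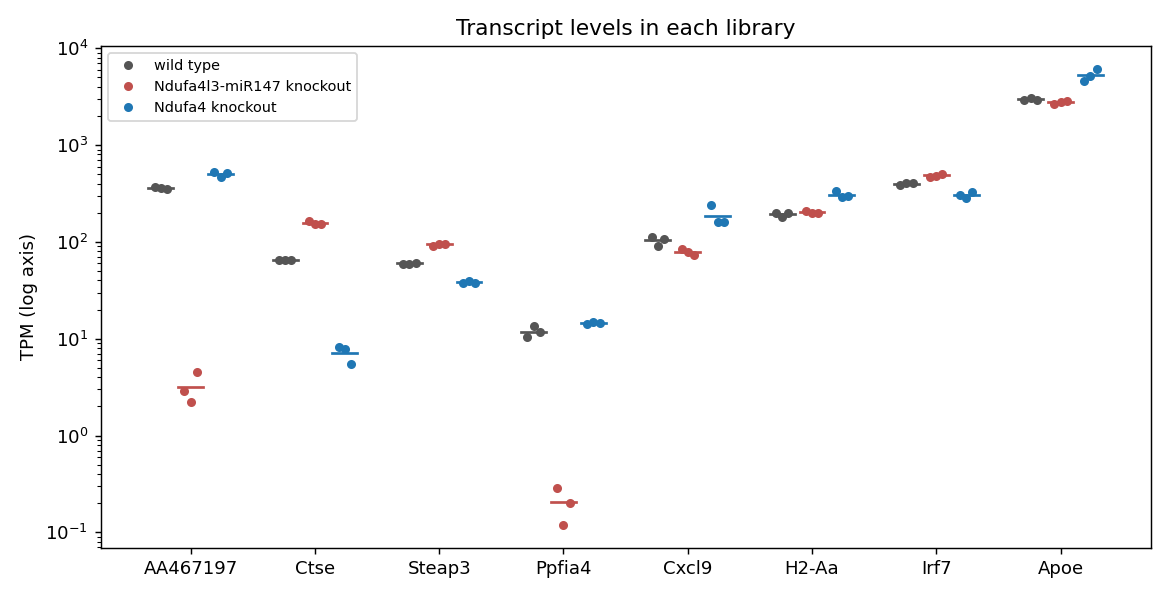
TPM on a log axis of 8 genes in each of the 9 libraries, with points for libraries, bars for means over 3 libraries and colour for genotype. AA467197 and Ppfia4 lie at 3.21 and 0.203 TPM in the Ndufa4l3-miR147 knockout, and Ctse lies at 156 TPM in that knockout and 7.19 TPM in the Ndufa4 knockout, with wild type at 64.8 TPM between them.

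Some chemokine transcripts were called higher in the Ndufa4l3-miR147 knockout, while 21 of 25 list members were not called and the list median was 0.041. Of 25 chemokines and cytokines measured, 4 rose and 0 fell (7 rose when adjusted over the list alone): Ccl7 by 0.66 ± 0.09, Ccl4 by 0.58 ± 0.07, Ccl9 by 0.41 ± 0.06 and Ccl2, a monocyte attractant at 848 ± 18.0 TPM, by 0.35 ± 0.05, the last named after its value was seen. The list passed camera upward (adjusted p = 4.2e-04; adjusted p = 0.32 with an estimated correlation), and its adjusted p was 0.085 without the filter on low values. No member stayed called without wild-type replicate 1, 2 or 3 or without Ndufa4l3-miR147 knockout replicate 2 or 3, and 2 did without replicate 1 of that knockout.

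Cholesterol synthesis transcripts were lower. Of 24 members 1 fell and 0 rose (13 fell when adjusted over the list alone), with 0 called without any 1 wild-type library or Ndufa4l3-miR147 knockout replicate 2 or 3, and the median change was -0.30. The list passed camera downward (adjusted p = 7.9e-19; adjusted p = 0.073 with an estimated correlation). Glycolysis transcripts were higher, with Slc16a3, the lactate exporter, up by 0.53 ± 0.06 to 248 ± 10.2 TPM and Slc2a1, the glucose transporter, up by 0.32 ± 0.05, 2 of 22 members, with 7 that rose and 1 that fell when adjusted over the list alone. This list passed camera upward (adjusted p = 2.2e-04; adjusted p = 0.073 with an estimated correlation). Both lists also passed fry (adjusted p = 0.0041 for each), and the other 6 lists called in this comparison did not (adjusted p of 0.059 to 0.91). Slc2a1 lost its call without any 1 library of the genotypes compared (limma adjusted p of up to 0.21), and without Ndufa4 knockout replicate 3 there were 9 cholesterol synthesis genes that fell and 7 glycolysis genes that rose (2 and 4 without replicate 1 of that knockout, and 2 of the former without replicate 2).

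Few interferon genes were called. Of 57 type I interferon-stimulated genes, Oasl1 rose by 0.40 ± 0.06 to 72.9 ± 3.51 TPM and 0 fell (5 rose when adjusted over the list alone). Oasl1 was not called without any 1 wild-type library or Ndufa4l3-miR147 knockout replicate 2 or 3 (limma adjusted p of up to 0.13), while 5 members rose without Ndufa4 knockout replicate 3. The list had a median of 0.07 and a camera adjusted p of 3.0e-06 (adjusted p = 0.69 with an estimated correlation). Of 46 members of the interferon-gamma response 0 were called by limma (6 when adjusted over the list alone, 3 in each direction, and 1 that rose without Ndufa4 knockout replicate 3), and the list was not called (camera adjusted p = 0.44). Gbp2, a guanylate-binding protein at 3306 ± 101 TPM, differed by -0.14 ± 0.07 and Iigp1 by -0.03 ± 0.09.

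Immediate early and hypoxia response genes passed camera upward (adjusted p = 3.0e-06 and 5.7e-05; adjusted p = 0.20 and 0.32 with an estimated correlation), each with 0 members called over all genes and 4 that rose when adjusted over the list alone. Cell cycle genes passed downward (adjusted p = 0.011; adjusted p = 0.95 with an estimated correlation) with 0 of 36 members called either way, and not without Ndufa4l3-miR147 knockout replicate 3 (adjusted p = 0.093). The NF-kB and Toll-like receptor pathway passed downward (adjusted p = 0.034; adjusted p = 0.32 with an estimated correlation) with 2 members that fell when adjusted over the list alone, and was lost without wild-type replicate 1 or 3, Ndufa4l3-miR147 knockout replicate 3 or Ndufa4 knockout replicate 3 (adjusted p = 0.074, 0.11, 0.093 and 0.091). In all it was lost in 10 of 23 alternatives, among them fry (adjusted p = 0.23), quantile normalization (0.072), a fit to only the 6 libraries compared (0.095) and removal of the length and GC trend (0.17). Without Ndufa4 knockout replicate 3 1 immediate early and 2 hypoxia response genes were called higher and 2 members of each of the other 2 lists lower. Respiratory chain lists did not pass: the camera adjusted p was 0.74 for 36 complex IV subunits and assembly factors, 0.75 for complex I, 0.17 for complexes II, III and V and 0.94 for mitochondrially encoded transcripts, with 0 members called by limma in each. Of the lists not called, lipid handling came closest (adjusted p = 0.058, called downward in 4 of 23 alternatives), with Gpnmb, a lysosomal glycoprotein at 1397 ± 37.9 TPM, falling by -0.28 ± 0.04. The call of Gpnmb was lost with median-of-ratios scaling (limma adjusted p = 0.16) and without any 1 library of the genotypes compared. Tgm2, a transglutaminase on the alternative activation list, rose by 0.33 ± 0.03 to 872 ± 1.99 TPM, and lost its call without any 1 wild-type library or Ndufa4l3-miR147 knockout replicate 2 (limma adjusted p of 0.052 to 0.056). The lists not called had camera adjusted p between 0.058 and 0.96.

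The second comparison set the Ndufa4 knockout against wild type, and it likewise cannot tell an effect of the loss from other differences between the cells. Ctse fell from 64.8 ± 0.695 to 7.19 ± 1.48 TPM, or -3.02 ± 0.12. Slco4a1 fell by -2.10 ± 0.20, Hpgd (which inactivates prostaglandins) by -1.52 ± 0.16, Gdf15 (a stress-induced cytokine) by -1.34 ± 0.14, the chemokine receptor Cxcr4 by -1.33 ± 0.09 and the desaturases Scd2 and Fads2 by -1.24 ± 0.14 and -1.19 ± 0.09. Tmeff1 rose by 1.12 ± 0.11, the integrin Itgax by 1.01 ± 0.11, Id1 by 0.999 ± 0.0997 and Upp1 (uridine phosphorylase) by 0.91 ± 0.07 to 153 ± 9.23 TPM. The limma adjusted p of these genes lay between 1.1e-05 and 0.0014, and each kept its call in every alternative.

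In all, 956 of 11133 genes were called, 315 higher and 641 lower, and 33 changed at least 2-fold, 6 upward and 27 downward. The share of calls that were higher, 33.0%, was 52.1% with median-of-ratios scaling or quantile normalization and 24.4% with the length and GC trend of each library removed. The median of all genes was -0.08, and -0.01 with median-of-ratios scaling. Leaving out wild-type replicate 1, 2 or 3 gave 266, 266 and 290 calls, leaving out Ndufa4l3-miR147 knockout replicate 2 or 3 gave 591 and 632, and leaving out Ndufa4 knockout replicate 3 gave 1586. When only the 6 libraries compared were fitted 238 genes were called, fewer than the 306 of the first comparison, so the order of both counts rests on the pooled spread. The rank correlation of these fold changes with transcript length across 11049 genes was -0.312, and -0.0392 without Ndufa4 knockout replicate 3.

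Type I interferon-stimulated genes were lower in the Ndufa4 knockout. Of 57 members, 18 fell and 1 rose, and 37 fell and 2 rose when adjusted over the list alone. Ifitm3, which restricts viral entry, fell by -0.41 ± 0.05 from 3734 ± 49.7 TPM, the secreted glycoprotein Lgals3bp by -0.35 ± 0.04, the membrane protein Ms4a4c by -0.73 ± 0.10 and Irf7, the transcription factor of the type I response, by -0.38 ± 0.06. Oasl1 rose by 0.21 ± 0.06, and lost its call without any 1 library other than Ndufa4 knockout replicate 3 (limma adjusted p of up to 0.17). Camera gave an adjusted p of 3.6e-08 (adjusted p = 0.59 with an estimated correlation) and fry one of 0.017. The number that fell was 7 without wild-type replicate 2 or 3, 10 without wild-type replicate 1, 22 without Ndufa4 knockout replicate 3 and 28 without Ndufa4 knockout replicate 1.

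MHC class II transcripts were higher. Of 14 members, 4 rose and 0 fell (6 rose and 1 fell when adjusted over the list alone): H2-Aa by 0.67 ± 0.06 to 308 ± 23.5 TPM, H2-Ab1 by 0.51 ± 0.07, the invariant chain Cd74 by 0.43 ± 0.06 to 1161 ± 91.6 TPM and H2-DMb1 by 0.37, the last named after its value was seen. The list passed camera (adjusted p = 1.1e-04; adjusted p = 0.056 with an estimated correlation). Members of the interferon-gamma response went both ways. Of 46, 3 rose and 5 fell (8 and 12 when adjusted over the list alone), with Upp1 and the T-cell attractant Cxcl9 up by 0.91 ± 0.07 and 0.82 ± 0.15 and Gbp11 and the protease inhibitor Serpina3f down by -1.12 ± 0.10 and -0.46 ± 0.06. The list was not called (camera adjusted p = 0.89, direction up, against a median of -0.03). Without Ndufa4 knockout replicate 3 there were 6 that rose and 8 that fell, and 8 fell without replicate 1. With the length and GC trend removed 4 rose and 10 fell. Without any 1 library of wild type or of the other knockout 2 or 3 fell, and 1 rose without wild-type replicate 2 or 3. Cxcl9 lost its call without these 2 (limma adjusted p = 0.069 and 0.052). Of 23 class I genes 3 fell, all of the H2-Q family, whose members share sequence (H2-Q4 by -0.37 ± 0.05 and H2-Q6 by -0.60 ± 0.09). The list was not called by camera (adjusted p = 0.21; adjusted p = 0.95 with an estimated correlation), but it passed fry downward (adjusted p = 0.049) and was called in 6 of 23 alternatives. Of these, leaving out Ndufa4 knockout replicate 3 gave 6 genes that fell (camera adjusted p = 0.0058) and removing the length and GC trend gave 9.

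**Figure D3:**
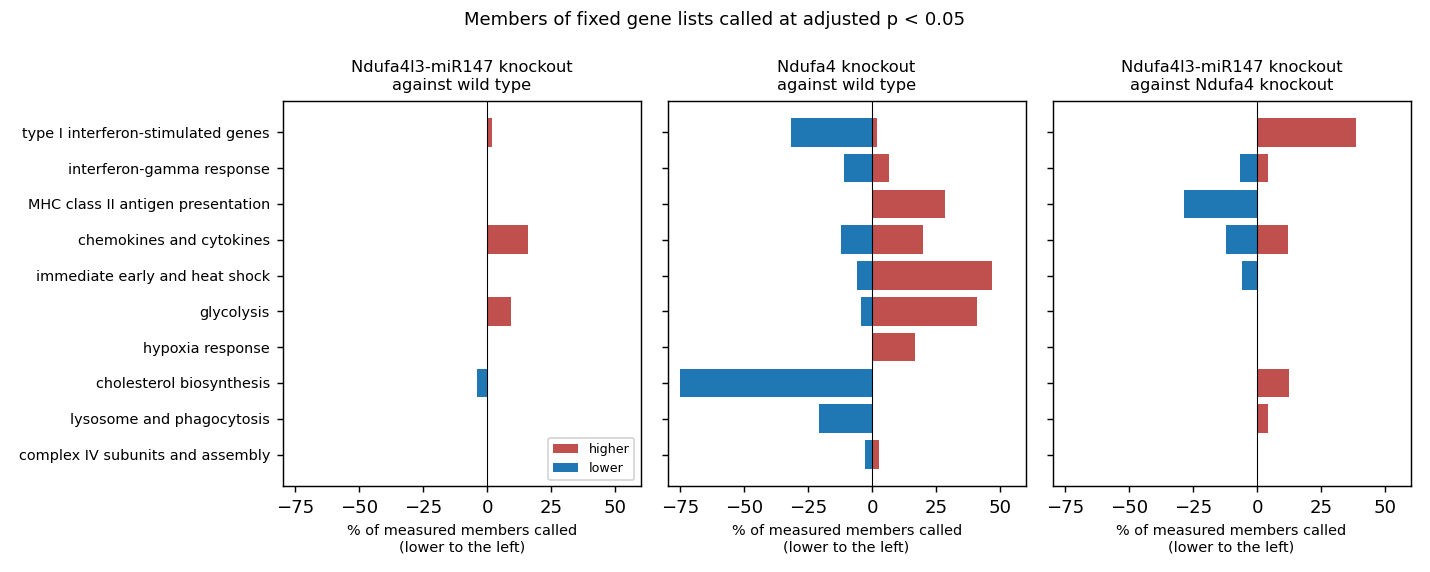
Percent of the measured members of 10 fixed gene lists that were called in each of the 3 comparisons, with higher members to the right in red and lower members to the left in blue. For the Ndufa4 knockout against wild type, 18 of 24 cholesterol synthesis genes and 18 of 57 type I interferon-stimulated genes were lower, and 4 of 14 MHC class II genes were higher.

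Of 24 cholesterol synthesis genes 18 fell and 0 rose (21 fell when adjusted over the list alone), with a median of -0.56 (camera adjusted p = 1.4e-13; adjusted p = 0.056 with an estimated correlation). Cyp51, a demethylase of the pathway, fell by -0.88 ± 0.08. The number that fell was 11 without wild-type replicate 1 and 12 without wild-type replicate 3. Of 19 lipid handling genes 3 rose and 6 fell, and the list was not called (camera adjusted p = 0.89). Without any 1 library of wild type or of the other knockout 2 or 3 of these fell, 1 rose without wild-type replicate 1 or 2, and 5 rose without Ndufa4 knockout replicate 3. Apoe, the apolipoprotein, rose by 0.82 ± 0.09 to 5303 ± 767 TPM, while the desaturases Scd1 and Scd2 fell by -1.11 ± 0.13 and -1.24 ± 0.14.

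Glycolysis genes were higher, with 9 of 22 called up and 1 down (11 and 3 when adjusted over the list alone). Slc16a3 rose by 0.56 ± 0.06 and Pgk1 by 0.23 ± 0.03, while Hk1, hexokinase 1, fell by -0.30 ± 0.05, and not without wild-type replicate 1 or 2 (limma adjusted p = 0.060 and 0.059). The camera adjusted p was 2.0e-06 (adjusted p = 0.052 with an estimated correlation). The number that rose was 3 without wild-type replicate 3 and 4 without wild-type replicate 1 or 2, and the number that fell was 2 and 3 without Ndufa4 knockout replicate 2 and 3. Of 18 hypoxia response genes 3 rose, among them Bnip3 by 0.55 ± 0.11 and Egln1 by 0.30 ± 0.07 (camera adjusted p = 0.028; adjusted p = 0.70 with an estimated correlation), with the call of the list lost without Ndufa4 knockout replicate 1 or 2 (adjusted p = 0.059 and 0.097) and 0 members called without any 1 wild-type library. There was 1 without Ndufa4 knockout replicate 1 or 2 or replicate 2 or 3 of the other knockout, and there were 5 without Ndufa4 knockout replicate 3. Of 17 immediate early and heat shock genes 8 rose and 1 fell (9 and 1 when adjusted over the list alone), with Myc up by 0.82 ± 0.08 and Fos by 0.83 ± 0.11. Camera gave an adjusted p of 3.6e-07 (adjusted p = 0.12 with an estimated correlation), and 2 or 3 members rose without any 1 wild-type library and 5 without Ndufa4l3-miR147 knockout replicate 1 or 2. No member was called lower without any 1 library of wild type or of the other knockout.

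Of 25 chemokines and cytokines 5 rose and 3 fell (10 and 5 when adjusted over the list alone), among them Cxcl16 by 0.40 ± 0.05, Tnf by 0.36 ± 0.06 and Il10 by -0.61 ± 0.12 (camera upward, adjusted p = 0.0023; adjusted p = 0.38 with an estimated correlation). Without wild-type replicate 1, 2 or 3 there were 3, 3 and 2 members that rose, and 1 fell without wild-type replicate 2, Ndufa4l3-miR147 knockout replicate 1 or Ndufa4 knockout replicate 2. Without wild-type replicate 1 or 3 no member was called lower, and Il10 had a limma adjusted p of 0.053 and 0.063. Without the filter on low values the adjusted p was 0.15. Of 14 T-cell co-signalling ligands 4 rose and 1 fell, with the inhibitory receptor Havcr2 up by 0.43 ± 0.07 (camera adjusted p = 0.0077; adjusted p = 0.62 with an estimated correlation, and adjusted p = 0.10 without the filter), and 1 member rose without any 1 wild-type library or Ndufa4l3-miR147 knockout replicate 3 and 2 without replicate 1 or 2 of either knockout. Of 17 nucleic acid sensing genes 3 fell, with Tlr7, the endosomal receptor of single-stranded RNA, down by -1.08 ± 0.22 from 68.8 ± 2.11 TPM and the RNA editor Adar by -0.32 ± 0.07 (camera adjusted p = 0.045; adjusted p = 0.71 with an estimated correlation). The list lost its call without wild-type replicate 3 or Ndufa4 knockout replicate 2 (adjusted p = 0.11 for each) and without any 1 library of the Ndufa4l3-miR147 knockout (adjusted p of 0.050 to 0.053), and both genes lost theirs without any 1 wild-type library. Without Ndufa4 knockout replicate 3 there were 6 that fell. Of 24 lysosome and phagocytosis genes 5 fell and 0 rose, among them Atp6v0d1 by -0.19 ± 0.04 (camera adjusted p = 0.022; adjusted p = 0.21 with an estimated correlation), and not with median-of-ratios scaling (adjusted p = 0.13) or without Ndufa4 knockout replicate 2 (adjusted p = 0.056). No member stayed called without any 1 library of wild type or of the other knockout, while 12 fell without Ndufa4 knockout replicate 3, 8 without replicate 1 and 11 with the length and GC trend removed. Cd14, the co-receptor of lipopolysaccharide, fell by -0.84 ± 0.06, in an NF-kB and Toll-like receptor list of which 4 fell and 1 rose. The list was not called by camera (adjusted p = 0.89) but passed fry downward (adjusted p = 0.038), and 1, 2 and 1 fell and 0 rose without wild-type replicate 1, 2 and 3, while 2 rose without Ndufa4 knockout replicate 3. Of the 14 lists called in this comparison 7 did not pass fry (adjusted p of 0.068 to 0.71).

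Of 97 entries on the cytosolic ribosomal protein list 5 rose and 1 fell. The one that fell was the kinase Rps6ka1, which is not a ribosomal protein, and Rpl12 rose by 0.47 ± 0.08. There were 0 entries called without wild-type replicate 2 or 3, 1 or 2 that rose without wild-type replicate 1 or any 1 library of the other knockout, and 11 and 15 without Ndufa4 knockout replicate 1 and 2. The camera adjusted p was 5.1e-12 (adjusted p = 0.62 with an estimated correlation). Mitochondrially encoded transcripts passed upward (adjusted p = 9.0e-05; adjusted p = 0.62 with an estimated correlation), with 1 of 13 called, mt-Nd3 by 0.27 ± 0.06, and not without any 1 wild-type library (limma adjusted p of 0.094 to 0.10) or Ndufa4l3-miR147 knockout replicate 2 (0.052), while 5 rose without Ndufa4 knockout replicate 2. The mitochondrial ribosome passed upward (adjusted p = 0.0046; adjusted p = 0.73 with an estimated correlation), with 4 of 77 rising, among them Mrpl52 by 0.51 ± 0.06, and 1 falling (1 or 2 and 0 without any 1 wild-type library), and the list lost its call without Ndufa4 knockout replicate 3 (adjusted p = 0.89). Complexes II, III and V passed upward with 0 of 29 members called (adjusted p = 0.045; adjusted p = 0.89 with an estimated correlation), and not without that library (adjusted p = 0.93, with the direction turned) or wild-type replicate 3 (adjusted p = 0.16). Of 36 complex IV subunits and assembly factors Cox7c differed by 0.21 ± 0.05 and Cox7a2l by -0.16 ± 0.04, both called and both lost without any 1 library of wild type or of the other knockout, with 2 called each way without Ndufa4 knockout replicate 3, and neither this list nor complex I was called (camera adjusted p = 0.19 and 0.057). Complex I was called upward in 8 of 23 alternatives, among them median-of-ratios scaling (adjusted p = 0.025) and leaving out wild-type replicate 1 or 2 (0.031 and 0.028) or Ndufa4 knockout replicate 1 or 2 (2.9e-05 and 0.018). Its direction turned without Ndufa4 knockout replicate 3 (adjusted p = 0.65) and with the length and GC trend removed (0.89). Complex IV was called without Ndufa4 knockout replicate 1 (adjusted p = 0.018). In Ndufa4 knockout replicate 3 the 2763 genes with the shortest transcripts deviated by a median of 0.11 and the 2761 with the longest by -0.39. Mitochondrially encoded transcripts made up 5.78%, 4.67% and 4.79% of replicates 1 to 3 of that knockout, and that list and the cytosolic ribosomal one kept their calls without replicate 3.

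The remaining lists were not called in this comparison, with camera adjusted p of 0.094 for the cell cycle (3 of 36 rose and 6 fell, among them Mcm2 by 0.34 ± 0.05 and Ccnb2 by -0.48 ± 0.07; 1 rose and 1 to 3 fell without any 1 wild-type library, 16 fell without Ndufa4 knockout replicate 1 and 6 rose without replicate 3; the list was called downward in 5 of 23 alternatives, with adjusted p = 0.013 without replicate 1 and 0.042 with median-of-ratios scaling), 0.77 for antimicrobial effectors, 0.77 for replication-dependent histones, 0.91 for inflammasome and cell death, for alternative activation and for the antioxidant and NRF2 response, 0.92 for the TCA cycle and fatty acid oxidation, 0.95 for the integrated stress response and 0.96 for mitochondrial and ER chaperones. Among marker lists the adjusted p was 0.91 for macrophages, neutrophils, and stromal and endothelial cells, 0.71 for monocytes, 0.77 for dendritic cells and 0.20 for osteoclasts. Clec9a, a marker of conventional dendritic cells, rose by 0.98 ± 0.19 to 55.2 ± 17.4 TPM, and not without any 1 wild-type library (limma adjusted p of 0.062 to 0.072). Neutrophil S100a9 was at 22.1 ± 18.9 TPM in wild type and 9.56 ± 8.24 TPM in the Ndufa4 knockout, and haemoglobin Hba-a2 at 46.1 ± 62.3 and 15.6 ± 17.1 TPM, with spreads as wide as the means. Of lymphocyte markers Ighm fell by -0.61 ± 0.07 in the Ndufa4 knockout, while Cd3e was at 0.0259 ± 0.0449 TPM in wild type.

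The third comparison set the knockouts against each other, which leaves wild type out of the difference. Ctse was 4.27 ± 0.12 higher in the Ndufa4l3-miR147 knockout than in the Ndufa4 knockout, Wdfy1 1.31 ± 0.14, Steap3 1.29 ± 0.05 and Lipg, endothelial lipase, 1.17 ± 0.08. Beside the target, Ppfia4 was lower by -3.69 ± 0.11, the interferon-induced chemokine Cxcl9 by -1.21 ± 0.15, Bst1 by -1.01 ± 0.07 and Apoe by -0.93 ± 0.09. The limma adjusted p of these genes lay between 2.4e-07 and 0.0052, and each kept its call in every alternative.

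In all, 361 of 11133 genes were called, 245 higher and 116 lower in the Ndufa4l3-miR147 knockout, and 18 differed at least 2-fold. The share of calls that were higher, 67.9%, was 49.3% with median-of-ratios scaling, 50.8% with quantile normalization and 81.8% with the length and GC trend removed. Leaving out 1 library of the Ndufa4l3-miR147 knockout gave 82, 92 and 94 calls, 1 wild-type library 185, 176 and 200 calls, and Ndufa4 knockout replicate 3 gave 740, while 64 genes were called when only the 6 libraries compared were fitted.

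Type I interferon-stimulated genes separated the knockouts. Of 57 members 22 were higher and 0 lower in the Ndufa4l3-miR147 knockout (44 higher when adjusted over the list alone). Irf7 stood at 488 ± 16.1 TPM against 307 ± 23.3 TPM, a difference of 0.67 ± 0.06, and Ms4a4c was higher by 1.06 ± 0.10. Camera gave an adjusted p of 1.7e-19 (adjusted p = 0.24 with an estimated correlation) and fry one of 0.0047. The number higher was 4, 6 and 5 without replicate 1, 2 or 3 of the Ndufa4l3-miR147 knockout, 13 without wild-type replicate 2 and 15 with median-of-ratios scaling. MHC class II genes went the other way, with 4 of 14 lower, among them H2-Aa by -0.60 ± 0.06 and Cd74 by -0.56 ± 0.06 (camera adjusted p = 2.1e-05; adjusted p = 0.11 with an estimated correlation). Of 46 interferon-gamma response genes 2 were higher and 3 lower, with Gbp11 at 0.88 ± 0.10 and Upp1 at -0.65 ± 0.07, and the list was not called (camera adjusted p = 0.39). The number higher was 1 without any 1 library of wild type or of the Ndufa4l3-miR147 knockout or Ndufa4 knockout replicate 2, and 5 and 4 without Ndufa4 knockout replicate 1 and 3. Chemokines were split as well, with Ccl9 higher by 0.64 ± 0.06 and Cxcl16 lower by -0.40 ± 0.05 (3 higher, 3 lower of 25, camera adjusted p = 0.66), and 1 was higher without Ndufa4l3-miR147 knockout replicate 1 and 5 without Ndufa4 knockout replicate 3.

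Of 24 cholesterol synthesis genes 3 were higher in the Ndufa4l3-miR147 knockout (10 when adjusted over the list alone), among them Cyp51 by 0.50 ± 0.08 (camera adjusted p = 2.1e-05; adjusted p = 0.29 with an estimated correlation), and 0 stayed called without replicate 1 or 2 of that knockout and 1 without replicate 3. There were 9 without Ndufa4 knockout replicate 3 or with the length and GC trend removed, and 6 without Ndufa4 knockout replicate 2. Lysosome and phagocytosis genes passed camera upward (adjusted p = 0.0066; adjusted p = 0.21 with an estimated correlation) with 1 of 24 called. There were 0 without any 1 library other than Ndufa4 knockout replicate 1 or 3, 3 and 8 without these, and 7 with the length and GC trend removed, and the list lost its call with median-of-ratios scaling (adjusted p = 0.097) and without Ndufa4l3-miR147 knockout replicate 3 (adjusted p = 0.055). Glycolysis genes passed camera downward, which compares them with the other genes, with 0 of 22 called (adjusted p = 0.0043; adjusted p = 0.21 with an estimated correlation). They did not pass fry (adjusted p = 0.095), their median was -0.06 against 0.07 for all genes, and the list was not called with quantile normalization (adjusted p = 0.40). Immediate early genes passed camera downward with 1 of 17 called, Myc by -0.43 ± 0.08 (adjusted p = 0.0035; adjusted p = 0.46 with an estimated correlation), and not without Ndufa4 knockout replicate 3 (adjusted p = 0.11). Myc lost its call without any 1 wild-type library (limma adjusted p of 0.056 to 0.060) and without Ndufa4l3-miR147 knockout replicate 1 or 2 (0.11 for each). Cxcr4 was higher by 1.07 ± 0.09. Of 23 integrated stress response genes 6 were higher, among them Gdf15 by 1.11 ± 0.14, and 0 lower (8 and 2 when adjusted over the list alone). The list was not called (camera adjusted p = 0.28; called in 2 of 23 alternatives). The number higher was 2, 2 and 1 without replicate 1, 2 and 3 of the Ndufa4l3-miR147 knockout, 2 with median-of-ratios scaling and 9 without Ndufa4 knockout replicate 3, with 1 lower.

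Cytosolic ribosomal proteins (camera adjusted p = 1.1e-18; adjusted p = 0.46 with an estimated correlation) and mitochondrially encoded transcripts (adjusted p = 6.1e-06; adjusted p = 0.54 with an estimated correlation) passed downward in the Ndufa4l3-miR147 knockout, and neither passed fry (adjusted p = 0.27 for each). Of 97 entries on the first list Rpl14 was lower by -0.26 ± 0.06 and the kinase Rps6ka2, which is not a ribosomal protein, higher by 0.44 ± 0.09, and of 13 mitochondrial ones mt-Nd3 was lower by -0.29 ± 0.06. Each of these 3 lost its call without any 1 library of wild type or of the Ndufa4l3-miR147 knockout (limma adjusted p of up to 0.16), the first 2 also without Ndufa4 knockout replicate 2 and mt-Nd3 without replicate 1. On the ribosomal list 8, 10 and 2 entries were lower without Ndufa4 knockout replicate 1, 2 and 3, and 2 mitochondrial transcripts were lower without replicate 2. Complexes II, III and V, the mitochondrial ribosome, complex I and complex IV passed downward as well (adjusted p = 3.1e-04, 6.0e-04, 0.0085 and 0.044; adjusted p = 0.54, 0.54, 0.69 and 0.54 with an estimated correlation). Each of the last 4 lost its call without Ndufa4 knockout replicate 3 (adjusted p = 0.40, 0.71, 0.73 and 0.80), the library with higher values of short transcripts, and with the length and GC trend removed (adjusted p = 0.0845, 0.167, 0.758 and 0.653). Complex I and complex IV also lost it without Ndufa4l3-miR147 knockout replicate 1 (adjusted p = 0.067 and 0.11), and complex IV without wild-type replicate 1 or Ndufa4l3-miR147 knockout replicate 3 (adjusted p = 0.051 and 0.055). Mitochondrially encoded transcripts lost their call with quantile normalization (adjusted p = 0.059). Of the 12 lists called between the knockouts 8 did not pass fry (adjusted p of 0.095 to 0.78). The lists not called had camera adjusted p between 0.072 and 0.85, with nucleic acid sensing and MHC class I each called upward in 6 of 23 alternatives. MHC class I and macrophage markers passed fry upward (adjusted p = 0.045 and 0.0056). Of 19 macrophage markers 5 were higher and 2 lower when adjusted over the list alone.

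Both knockouts were then compared in their changes against wild type. Across the 11133 genes, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.407 and a Spearman rho of 0.434. Draws in which all 9 libraries were simulated unchanged, with 1 spread per gene for all genotypes, gave 0.499 and 0.463 on average. Real spreads were unequal. Median log2 distances within a genotype were 0.0624 to 0.073 for wild type and 0.129 to 0.221 for the Ndufa4 knockout. The simulation may overstate the spread of the controls, so it cannot show what shared controls alone give. The covariance was 0.0224, against 0.0142 in the simulation, a difference of 0.00818. Of the genes called, 26 changed the same way in both knockouts, 15 up and 11 down, where independent lists would share 0.764 and 1.21. These lists are not independent, since both comparisons share their controls and 3 wild-type libraries cannot be split into parts of at least 2, so the size of the overlap was not tested. Shared rises included Tmeff1 (0.88 ± 0.11 in the Ndufa4l3-miR147 knockout and 1.12 ± 0.11 in the Ndufa4 knockout), Plau (0.77 ± 0.06 and 0.69), Slc16a3 (0.53 ± 0.06 and 0.56 ± 0.06) and Tgm2 (0.33 ± 0.03 and 0.49 ± 0.03). Shared falls included Slco4a1 (-1.49 ± 0.20 and -2.10 ± 0.20), Fads2 (-0.69 ± 0.09 and -1.19 ± 0.09) and Ighm (-0.65 ± 0.07 and -0.61 ± 0.07). The count was 5 without wild-type replicate 1 and 131 without Ndufa4 knockout replicate 3. Another 6 genes were called in opposite directions, where independent lists would give 2.15.

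Of these 6 genes, Ctse, Steap3 and 5430435G22Rik lie on chromosome 1 in a stretch of 15.6 Mb (GRCm38, 120113280 to 135752232) that held 7 of the 48 genes called in the Ndufa4l3-miR147 knockout. The others there were Dbi, Ppfia4, Ube2t and Csrp1. In the Ndufa4 knockout, 13 of the 67 genes measured there were called, or 19.4%, against 8.55% of genes elsewhere. The bounds of the stretch were set by the called genes themselves. Of these, Ctse, Steap3, 5430435G22Rik and Csrp1 were also called in the Ndufa4 knockout, against the same controls.

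**Figure D4:**
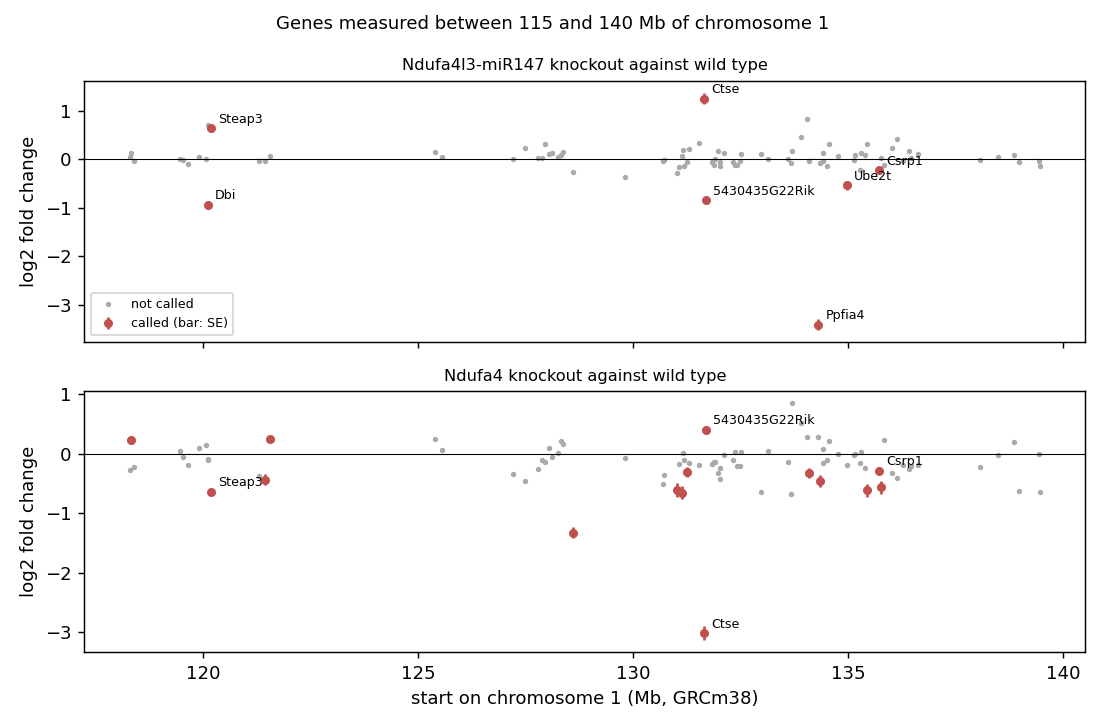
Log2 fold change against the start position on chromosome 1 (Mb, GRCm38) of the genes measured in and around the stretch, for the Ndufa4l3-miR147 knockout (top) and the Ndufa4 knockout (bottom) against wild type, with called genes in red with SE bars, other genes in grey, and names for those of the 7 genes called in the Ndufa4l3-miR147 knockout that were called in the panel. Ppfia4 lies at -3.41 in the top panel and Ctse at 1.25 in the top and -3.02 in the bottom panel.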

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

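The tests of a wrong genotype label, of the placement of calls on chromosome 1, of genes near the targeted loci, of single libraries and of dendritic cell markers were chosen after the results were seen, while those of transcript length, GC content and other splits of the libraries were written before.

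For 6 genes the changes against wild type were called in opposite directions in the knockouts. The genes were picked for this, so a difference between the knockouts follows from the choice and its p-value adds nothing. The difference was 4.27 for Ctse, 1.29 for Steap3, 1.17 for Lipg and 0.64 for Ccl9, each higher in the Ndufa4l3-miR147 knockout and lower in the Ndufa4 knockout than in wild type. It was -1.25 for 5430435G22Rik and -0.88 for Pla2g7, each with the directions exchanged. The calls of Lipg and Pla2g7 in the Ndufa4l3-miR147 knockout were lost without any 1 library of the genotypes compared (limma adjusted p of up to 0.175 and 0.132), and that of Ccl9 without any of these but Ndufa4l3-miR147 knockout replicate 1 (limma adjusted p of up to 0.15).

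Ndufa4 knockout replicate 3 stood apart, at a median distance of 0.221 on the log2 scale from the other 2 libraries of its genotype, where replicates 1 and 2 had 0.178 and 0.129 and the libraries of the other genotypes 0.0624 to 0.0871. A wrong genotype label was argued against, since 94% of 50 genes lay nearer to the Ndufa4 knockout. A difference in coverage by transcript length may account for part of it, with a Spearman rho of -0.535 between deviation and length across 11049 genes against at most 0.115 in size in the other genotypes, but the distance was still 0.186 (0.136 and 0.119 for replicates 1 and 2) after length and GC trends were removed. GC content gave 0.51 and cannot be told apart, since the largest other values, 0.544 in size for GC in replicate 1 and 0.427 for length in replicate 2, had the opposite sign and were measured against a mean that holds replicate 3. No biological explanation was tested, and whether RNA quality or the cells differed stays open, with 4 genes of the Y chromosome lowest in this library. Long transcripts were lower there in general, and these 4 genes were not examined with length and GC trends removed. Their levels therefore do not show that the cells differed.

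Of the 48 genes called in the Ndufa4l3-miR147 knockout, 7 lay within 15.6 Mb of chromosome 1, where 0.291 were expected. Chance placement was argued against by a share of 0.0007 of 10000 shuffles with as many calls in a window of that width, although the width was chosen from the data. Variants around the targeted gene were argued against, as it lies on chromosome 2 and the calls on chromosome 1. Reads lost to variants in the knockout could lower the 5 genes that fell. Reads lost to variants in wild type could raise the 2 others in the knockout. Whether wild type matched the reference there was not tested, so read loss stays open for all 7 genes. A second background segment that differs between the mice is a possible explanation that was not tested. In the Ndufa4 knockout 19.4% of the genes measured there were called, against 8.55% elsewhere. This share is not separate support. It includes Ctse, Steap3, 5430435G22Rik and Csrp1, by which the stretch was set, and both comparisons share their controls.

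In the Ndufa4 knockout 18 of 57 type I interferon-stimulated genes were lower, while 4 of 14 MHC class II genes were higher. Ndufa4 knockout replicate 3 alone was argued against, since 22 type I genes were lower without it, and so was a length and GC trend between libraries, since 33 were lower with it removed. Median-of-ratios scaling left 14, and the count was 7 without wild-type replicate 2 or 3. More dendritic cells could raise MHC class II transcripts, and 1 of 3 dendritic cell markers of at least 5 TPM was higher (Clec9a at 0.98, with Batf3 at 0.04 and Tcf4 at -0.28), which cannot tell. The rule for this last test was reworded to that verdict after its result had been seen, and an effect of the loss of Ndufa4 on interferon signalling stays open.

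The 6 libraries of each comparison can be split into groups of 3 in 10 ways, which cannot give a share under 0.05. For the Ndufa4l3-miR147 knockout against wild type the real split gave 48 called genes and at most 1 in another split, 7 and 1 at 2-fold, and 8 and 9 called lists, so that 1, 1 and 4 splits were as large. For the Ndufa4 knockout against wild type it gave 956 and 0 genes, 33 and 0 at 2-fold, and 14 and 16 lists, with 1, 1 and 3 splits as large. Between the knockouts it gave 361 and 2 genes, 18 and 2 at 2-fold, and 12 and 11 lists, with 1 split as large for each. In both comparisons against wild type another split gave more called lists than the real one. The number of lists called by camera at the preset correlation therefore does not set the genotypes apart from mixed groups there.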

How the results depend on the processing

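Of the named genes called, 3178 of 3819 values under alternatives kept direction and call, 641 lost the call and 0 reversed. These genes were chosen by size of change or adjusted p, and fewer calls held over all genes. Without wild-type replicate 1, 2 or 3, 13, 15 and 16 of the 48 calls in the Ndufa4l3-miR147 knockout were kept. In the Ndufa4 knockout 258, 262 and 286 of 956 were kept. Of the called lists, 662 of 778 kept both, 113 lost the call and 3 reversed. Values below are in the order Ndufa4l3-miR147 knockout against wild type, Ndufa4 knockout against wild type, and knockout against knockout, and the cause of a move was not tested unless named.

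Leaving out 1 library at a time gave 13 to 198, 266 to 1586 and 82 to 740 called genes, 3 to 12, 25 to 60 and 13 to 30 at 2-fold, 7 to 10, 12 to 16 and 9 to 13 lists, a correlation of 0.344 to 0.488 between the knockouts and 5 to 131 genes shared in direction. A pseudocount of 0.1 gave 61 genes at 2-fold in the Ndufa4 knockout, and one of 5, which shrinks fold changes by construction, gave 4, 8 and 11. With a filter at 5 TPM 4 genes were at 2-fold in the Ndufa4l3-miR147 knockout. Limma without a trend called 30 genes there and 16 shared genes. Only the 6 libraries compared gave 306, 238 and 64 genes and 12 at 2-fold in the Ndufa4l3-miR147 knockout. With an estimated correlation 0, 0 and 0 lists were called by camera, against 8, 14 and 12 at the preset one. The estimate was 0.00215 for glycolysis, 0.0062 for MHC class II and 0.00566 for lysosome and phagocytosis genes. These lie below the preset 0.01, so a higher correlation does not account for the lost calls of these lists. Fry called 2, 10 and 6.

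With the replicate number as a block 24, 661 and 162 genes and 15 shared genes were called. Residuals of same-number pairs correlated between -0.138 and 0.179, and 3 of 9 libraries were closest to their own number. These values show no clear pairing by number. They cannot exclude one, since residuals were taken within groups of 3 libraries.

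Chosen after seeing the data, library weights gave 538, 3045 and 1726 genes and 16, 72 and 71 at 2-fold. Ndufa4 knockout replicate 3 left out with median-of-ratios scaling gave 191, 1546 and 703 genes, 11 at 2-fold in the Ndufa4l3-miR147 knockout and 131 shared genes. Length and GC trends removed gave 70, 1436 and 708 genes.

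Complexes II, III and V in the Ndufa4 knockout turned to a median of -0.0298 without replicate 3 of that knockout, and reached 0.0657 without replicate 2. Complex I between the knockouts turned to 0.0450 without Ndufa4 knockout replicate 3 (-0.104 without replicate 1) and to 0.0118 with scaling as well. Macrophage markers in the Ndufa4 knockout had a median of -0.00821 and passed fry downward (adjusted p = 0.0035), while camera, which compares with the other genes, gave the direction up. Read depth is unknown from TPM, so what depth limits was not assessed.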

Other observations

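Levels of some further genes are given as mean ± SD. Bst1, an ectoenzyme of NAD metabolism, was at 25.1 ± 0.515 TPM in wild type, 21.7 ± 0.775 in the Ndufa4l3-miR147 knockout and 44.8 ± 3.07 in the Ndufa4 knockout. Ppfia4 was at 11.9 ± 1.52, 0.203 ± 0.0854 and 14.6 ± 0.299 TPM. Il7r was at 31.8 ± 2.04, 40.4 ± 2.56 and 35.3 ± 6.64 TPM, and Hbb-bs at 40.5 ± 49.3, 35.5 ± 19.8 and 12.95 ± 10.64 TPM, on marker lists that were too small to test.

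Actb, often used as a reference transcript, was at 4733 ± 35.9, 5177 ± 78.7 and 6093 ± 415 TPM, and it rose by 0.36 in the Ndufa4 knockout against wild type (limma adjusted p = 0.0046).

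The test of miR-147 seed sites was written before the result was seen, and those of genes near the targeted loci were chosen after it. The hypothesis that loss of miR-147 raises transcripts with a seed site was tested on 264 of 10572 genes with a 3 prime UTR that held CCGCACA. Their median change in the Ndufa4l3-miR147 knockout differed by -0.0019 from that of the others and ranked 41 of 60 among shuffled sites, whose highest value was 0.0231. By limma camera across the 10572 genes the p was 0.994. This speaks against a broad rise of such transcripts and leaves single targets open.

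The hypothesis that variants carried along with a targeted locus account for calls was tested within 10 Mb. Near Ndufa4l3, 1 of 169 genes was called (Sord, named after its value was seen), against 46 of 10879 elsewhere (Fisher exact p = 0.516). Near Ndufa4, 2 of 33 were called (Phf14 and Tfec, named after their values were seen), against 950 of 11016 (Fisher exact p = 1). The tests cannot tell, since few calls were expected near either locus, and the rule was reworded to that verdict after the result had been seen.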
